A study of Homo sapiens with 12 samples.

How the data were processed

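H3K27ac ChIP-seq was done with 1 antibody on 12 libraries of human pancreatic ductal adenocarcinoma lines, in 6 groups of 2: CFPAC1 untreated, CFPAC1 treated with 1000 U/ml of interferon beta (IFN-β) for 2 h, MiaPaCa2 untreated, MiaPaCa2 treated in the same way, CFPAC1 wild-type (WT) clones carrying an empty CRISPR vector, and CFPAC1 clones in which IRF1 was knocked out by CRISPR. Groups were taken from the sample labels. The labels do not state whether the libraries of a bulk group came from separate cultures. The limma p-values of single genes therefore measure the spread between these libraries, pooled over all 6 groups. A group without coverage at a gene adds almost no spread to that estimate. The clones are separate clones, but the p-values of their comparison rest partly on the spread between bulk libraries. Fisher's exact tests and matched lists count genes or loci, and camera sets the genes of a list against other genes. Genes and loci are not replicates, so the p-values of those tests do not measure replication across libraries. The labels also name more than 1 sequencing instrument without assigning libraries to it, so no batch could be tested.

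Per the labels, reads were trimmed with Trimmomatic 0.38, aligned to GRCh38 with Bowtie2 2.2.6 and handled with SAMtools, and peaks were called with MACS2 2.1.0.20150731. The deposited files are 1 narrowPeak list per library, so the authors did not pool replicates in them. The deposited score column equals 10 times the q column without its decimals and was not used. Each deposited peak has a fold enrichment ratio of its summit over the local background, a -log10 p and a -log10 q, all made by the authors for each library on its own; these values were used only to rank or filter peaks within a list. The smallest deposited -log10 q was 1.3 to 1.37, close to a q of 0.05. The control library, the filters and the read depth are not stated. Depth is therefore unknown, and no interval or floor that needs a read count was computed. A background level was solved from the deposited fold and p of 2000 sampled peaks per library, taking the summit pileup as a whole number to within 0.005 of the -log10 p. It lay between 1.02 and 1.83 in 11 libraries and could not be solved in IRF1 knockout clone 1, where 1.8% of the sampled peaks gave a whole number. Whether that library was scaled or its peaks were called with other options is not known. In every library 19.2 to 27.5% of peaks lay within 1 kb of an end of a protein-coding gene, against 4.6 to 5.9% after the peaks were shifted by 1 Mb, as a check of the genome build.

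Peaks on chromosomes 1 to 22 and X were used, which left out 0 to 55 peaks per library. For each of 4 comparisons the peaks of its 4 libraries were merged into loci. A locus was called gained or lost when both libraries of one group and neither library of the other held a peak in it by at least 1 bp. With 2 libraries against 2 there are 3 divisions of the libraries into pairs, so the smallest two-sided permutation share is 0.333 and no count of loci can reach p under 0.05. Each count is given beside the same count in the other 2 divisions. A locus was assigned to the nearest gene end within 50 kb. Lists of genes were tested for called loci by two-sided Fisher's exact test over genes with at least 1 assigned locus, with Benjamini-Hochberg adjustment over the lists in each direction, and again against 10000 random lists matched on the number of assigned loci. Overlaps between called loci of different comparisons were tested by two-sided Fisher's exact test over the loci found in both.

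The covered length of a gene is the number of bp under peaks within 5 kb either side of a gene end. The gene table gives no strand, so a gene start could not be told from a gene end. The end with the larger mean covered length over all 12 libraries, without regard to group, was used for each of 19974 protein-coding genes, and the larger end had over 5 times the coverage of the smaller in 10695 genes. Neighbouring genes can share a window, which is stated where a named pair does. Covered length measures how far peaks extend, not the height of the signal, and it cannot exceed the window. Genes covered in at least 2 libraries (15513) were analysed as log2 of covered bp plus 500 bp, centred on the mean of each library, with limma 3.58.1 under R 4.3.3: 1 model over the 6 groups with a trended prior and 6 residual degrees of freedom. Adjusted p-values of single genes are limma values with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation. Loci were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

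Before the data were examined, 21 gene lists were written down: interferon-stimulated genes, interferon signalling, antigen presentation, NF-κB and inflammatory genes, epithelial genes, endodermal transcription factors, genes of classical pancreatic tumours, mesenchymal genes, fatty acid oxidation, sterol and fatty acid synthesis, glycolysis and pentose phosphate genes, hexosamine and glycosylation genes, TCA cycle and respiration, glutathione and redox genes, amino acid metabolism, cell cycle, ribosomal proteins, markers of immune cells, of fibroblasts and endothelium, and of neuroendocrine and acinar cells, and genes often deleted in these lines. They hold 695 genes, of which 694 matched the gene table. The comparisons, tests and alternatives were also fixed before the data were examined, except where the text says otherwise. So was the rule for named genes: in each comparison the 8 loci in each direction with the largest smaller fold of the pair of libraries, the 6 called genes in each direction with the largest change in covered length, the 4 members with the largest change from each list that passed camera, and always a set of interferon, lineage and deletion genes that begins with IRF1. Not every gene that the rule picks is reported. All genes called in the difference between lines are named. Other list members named in the text were chosen after their values were seen.

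Both procedures were tested on simulated data built on the CFPAC1 libraries. All 200 gained and 200 lost loci planted among 120479 loci were found, which checks the computation and not the rule, since planted loci meet the rule by construction. Of 100 random lists 1 passed p under 0.05 by Fisher's test and 2 by the matched lists. The limma model found 65 of 100 genes with a planted log2 change of 1 and 98 of 100 with a change of 2, with 12 false calls, and 2 of 100 random lists passed camera. The simulated genes vary independently, so this does not test camera on lists whose members move together. Simulated values also had the same spread in every group, no floor for uncovered genes and no limit at the window. The numbers found and falsely called therefore do not carry over to genes that move from or to no coverage. The estimated correlation among interferon-stimulated genes was 0.329. The random lists were also not chosen to be rich in loci. Alternatives tried were a minimum -log10 q of 5, the same number of peaks in each library, other definitions of a locus and of its presence, all contigs, a 10 kb limit for gene assignment, a 2 kb window, pseudocounts of 100 and 2000 bp, no filter, no centring, quantile normalization, only the libraries of the comparison, a replicate block, and leaving out each library. Chosen after seeing the data were the whole gene with 5 kb flanks, both gene ends, and leaving out chromosome 20 or the 5 chromosomes whose share of peaks in a clone departed by over 15% from the other CFPAC1 libraries. A genome sequence was not used here, so the planned searches for 15 motifs, the interferon-stimulated response element among them, were left out. After seeing the data, 2 further analyses were run and left out because their construction partly fixes the outcome: the change after IFN-β against the coverage before it, which the limit of the window binds, and the overlap of loci called between clones with loci held by 1 line alone, since the clones are CFPAC1 cells.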

Results

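H3K27ac, a histone mark of active promoters and enhancers, was mapped in CFPAC1 and MiaPaCa2, lines from human pancreatic ductal adenocarcinoma that are usually described as low-grade and high-grade. Both lines were profiled untreated and after 2 h with IFN-β, a type I interferon. CFPAC1 was also profiled as WT clones and as clones without IRF1, a transcription factor of the interferon response that the study's title links to the metabolic programmes of low-grade cells. Each of the 6 groups has 2 libraries (n = 2 throughout). The peak lists held 59896 to 109861 peaks covering 63.6 to 94.8 Mb, and the read depth is unknown. Covered length (mean ± SD) was 89.8 ± 7.15 Mb in untreated CFPAC1, 76.8 ± 0.18 Mb in treated CFPAC1, 75.0 ± 4.55 Mb in untreated MiaPaCa2, 70.4 ± 9.55 Mb in treated MiaPaCa2, 80.7 ± 7.21 Mb in WT clones and 84.7 ± 8.61 Mb in IRF1 knockout clones. The Jaccard index of covered bp had a median of 0.652 between libraries of a group (0.576 to 0.691), 0.607 between groups of the same line and 0.28 between lines. All positions are on GRCh38.

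The treatment of CFPAC1 asked where a short exposure to IFN-β changes the acetylated regions of a low-grade line. Interferon-stimulated genes, which encode antiviral proteins and chemokines, gained H3K27ac coverage as a group. Their mean log2 change in covered length exceeded that of other genes by 0.96 (75 tested members, camera adjusted p = 1.92e-42), and 71 members had a positive fitted change (adjusted p = 0.224 with an estimated correlation). Over all genes 21 members rose and 0 fell, while 56 rose and 0 fell adjusted over the list alone. At CXCL11, which encodes a chemokine that attracts T cells, coverage went from 56 and 296 bp in the untreated libraries to 5785 and 3729 bp in the treated ones (log2 change 3.10 ± 0.25 SE, adjusted p = 6.59e-04). Its neighbour CXCL10 went from 4 and 414 bp to 5143 and 3058 bp (2.87 ± 0.32, adjusted p = 0.0048). CMPK2 and RSAD2, adjacent antiviral genes with a shared window, rose by 2.86 ± 0.33 and 2.76 ± 0.33 (adjusted p = 0.00483 and 0.00586). MX1, which encodes a GTPase that blocks viral replication, rose by 2.08 ± 0.27 (adjusted p = 0.00748), IFIT1, a sensor of viral RNA, by 1.68 ± 0.21 (adjusted p = 0.00662), and ISG15, a ubiquitin-like modifier, by 0.66 ± 0.13 (adjusted p = 0.0427).

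Genes of interferon signalling rose as a list in CFPAC1 (0.30 above other genes, 27 tested, camera adjusted p = 0.00612; adjusted p = 0.338 with an estimated correlation). Over all genes 2 members were higher, and 5 were higher and 1 lower adjusted over the list alone. Among them SOCS1, a feedback inhibitor of JAK kinases, rose by 2.07 ± 0.30 (adjusted p = 0.0145). STAT2 had 2283 and 2102 bp untreated and 3932 and 3841 bp treated (0.85 ± 0.17, adjusted p = 0.0525), and IRF8 had no coverage untreated and 322 and 544 bp treated (adjusted p = 0.0559). IRF1 was broadly covered before treatment, with 7777 and 6832 bp, and had 9044 and 8628 bp after it (0.41 ± 0.14, adjusted p = 0.258). IRF9 changed by 0.82 ± 0.32, IRF7 by 0.75 ± 0.41, IFIT3 by 0.54 ± 0.20 and OAS1 by 0.71 ± 0.32 on the log2 scale, none past the threshold (adjusted p = 0.312 to 0.563). The signalling list lost its call without IFN-β replicate 1 (adjusted p = 0.158), with the same number of peaks in each library (adjusted p = 0.0932) and without the filter on covered bp (adjusted p = 0.092).

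The antigen presentation list also rose in CFPAC1 (0.26 above other genes, 30 tested, camera adjusted p = 1.09e-05; adjusted p = 0.338 with an estimated correlation). Over all genes 2 members rose, and 10 rose adjusted over the list alone. TAP2, a peptide transporter, and PSMB8, an immunoproteasome subunit, share a window and rose by 0.78 ± 0.13 (adjusted p = 0.0198) and by 0.59 (adjusted p = 0.0291). NLRC5, the activator of class I genes, had 2917 and 2805 bp untreated and 5405 and 4474 bp treated (adjusted p = 0.0727), and HLA-C 960 and 845 bp against 1955 and 1460 bp (adjusted p = 0.143). HLA-G had no coverage untreated and 686 and 257 bp treated (adjusted p = 0.0735). PSMB9 (0.40, adjusted p = 0.171) and HLA-E (adjusted p = 0.918) did not pass.

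In CFPAC1 as a whole 105 genes gained and 48 lost covered length, of 15513 tested. Outside the lists, large gains were at LINGO1 (0 bp in both untreated libraries, 5982 and 3300 bp treated, adjusted p = 5.55e-04), IL1F10, an interleukin-1 family cytokine (0 bp untreated, 4932 and 2512 bp treated, adjusted p = 0.02), and MORC1 (0 bp untreated, 3432 and 2574 bp treated, adjusted p = 4.06e-04). TGM1, the transglutaminase of the epidermal barrier, rose as well (3.17 ± 0.45, adjusted p = 0.0113), as did SNX20 (2.88 ± 0.36, adjusted p = 0.00662). IDO1, which degrades tryptophan and belongs to the amino acid list, rose by 2.22 (adjusted p = 0.02). Coverage fell at CCDC33 (7451 and 4984 bp against 1172 and 1054 bp, adjusted p = 9.07e-04), CLDN11, a tight junction gene (-1.69 ± 0.25, adjusted p = 0.0145), and ARRB1, an arrestin (-1.65 ± 0.31, adjusted p = 0.0439). KRT14, a basal keratin, had 1216 and 1186 bp untreated and 0 bp in both treated libraries (adjusted p = 0.0176). B3GNT6, which builds mucin core glycans, had 2417 and 1503 bp untreated and 0 bp treated (adjusted p = 0.0427), but with the same number of peaks in each library its fitted change was 0.11 (adjusted p = 0.964). OMP had 1922 and 1671 bp untreated and 0 bp treated (adjusted p = 0.037). The other 18 lists, the metabolic, lineage and cell type lists among them, did not pass (camera adjusted p = 0.158 to 0.906). The lineage genes KLF5, ELF3, GATA6, CDH1, VIM and ZEB1 had fitted changes between -0.25 and 0.09 (adjusted p = 0.8 to 0.985), and the signs for GATA6, CDH1 and VIM, and for CDKN2A, turned with the scaling. Without centring 67 genes gained and 75 lost coverage, with the median of all genes shifted by -0.145. The count of 153 genes fell to 29 without untreated replicate 1 (24 gains and 5 losses), 40 without untreated replicate 2 (33 and 7), 3 without IFN-β replicate 1 (2 and 1) and 70 without IFN-β replicate 2 (38 and 32), and to 46 (38 and 8) with only the libraries of this comparison.

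**Figure D1:**
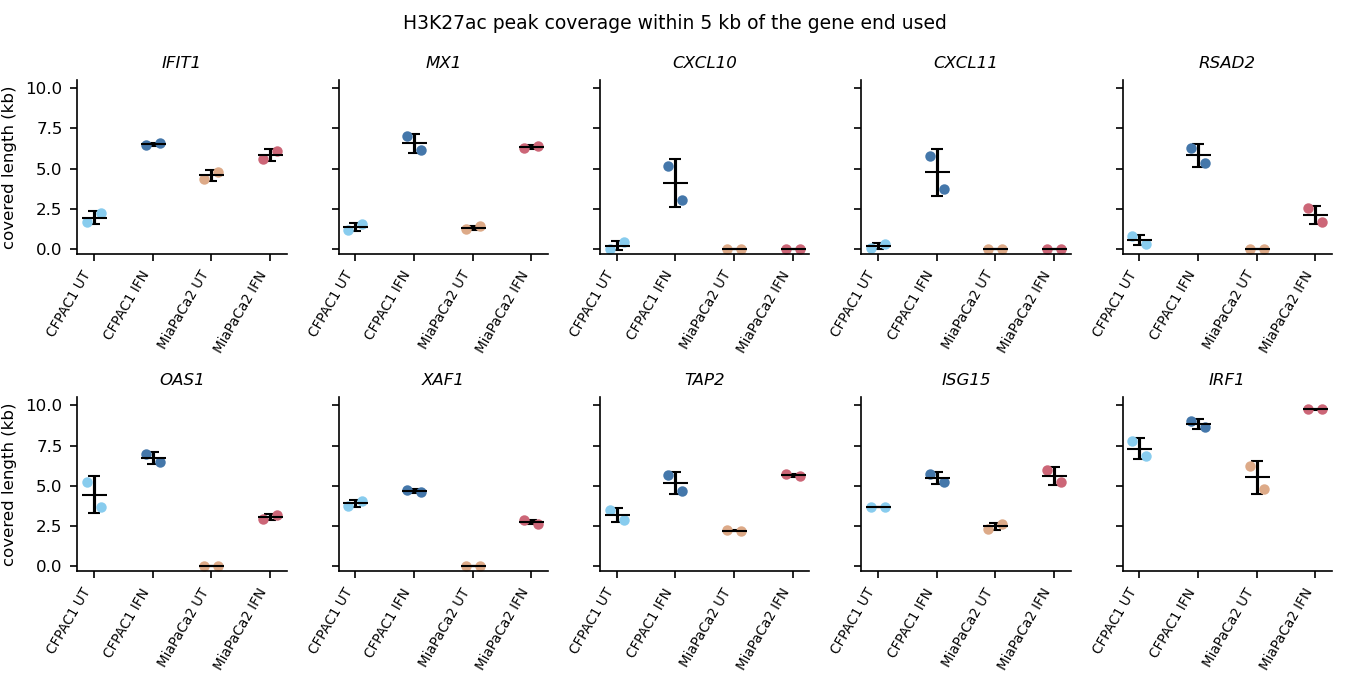
Covered length (kb, y axis) around 10 interferon-related genes in untreated (UT) and IFN-β-treated (IFN) libraries of both lines; points are the 2 libraries of a group, bars the mean and SD. CXCL10 went from 4 and 414 bp to 5143 and 3058 bp in CFPAC1 and stayed at 0 bp in MiaPaCa2, while XAF1 went from 0 bp to 2845 and 2648 bp in MiaPaCa2.

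Among 120479 loci in CFPAC1, 3340 were gained and 7743 lost after IFN-β, 11083 in all, against 5328 and 2711 in the other 2 divisions of the libraries. Gained loci lay near 35 of 76 interferon-stimulated genes with a locus (46.1%, against 9.1% of other genes; odds ratio 8.56, adjusted p = 1.17e-15), 4.42 times the number in lists matched for locus number (adjusted p = 0.0042, from the smallest p that the random lists can give). They also lay near 9 of 25 interferon signalling genes (odds ratio 5.55, adjusted p = 0.00264; matched adjusted p = 0.0399). Gained loci with the largest folds, as the authors computed them, were near TENM4 (chromosome 11, 78645135 to 78646737), MORC1 (chromosome 3, 109120405 to 109123242), RIGI, a sensor of viral RNA (chromosome 9, 32528331 to 32530826), ADPRH, OTOF, SOX13, THSD1 and THNSL1. The RIGI locus had folds of 15.4 and 16.4 in the treated libraries. Lost loci with the largest folds, near ZNF846, PIK3IP1, MKNK2, RGS9BP, PLB1, OLFML2A, EI24 and TCEAL3, were narrow, at 314 to 804 bp. Lost loci lay near 22 of 35 epithelial genes (odds ratio 5.29, adjusted p = 3.02e-05) and 12 of 22 endodermal transcription factors (odds ratio 3.74, adjusted p = 0.0233). These were 1.491 and 1.405 times the numbers in lists matched for locus number, neither past the threshold (adjusted p = 0.16 and 1). With the same number of peaks in each library 4641 loci were lost and 4161 gained. Without IFN-β replicate 1 the odds ratio at interferon-stimulated genes was 4.04, and gained and lost loci numbered 8113 and 11721. They numbered 5982 and 20771 without untreated replicate 2, 11160 and 12267 without IFN-β replicate 2, and 4550 and 26914 without untreated replicate 1, since a single library then defines a group.

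MiaPaCa2, the high-grade line, was treated in the same way to compare its response. Interferon-stimulated genes again gained coverage as a group, by 1.07 more than other genes (75 tested, camera adjusted p = 5.48e-71; adjusted p = 0.0667 with an estimated correlation). Over all genes 32 members rose and 0 fell, and 52 rose and 0 fell adjusted over the list alone. Several had no peak before treatment. OAS1, which makes the activator of an antiviral RNase, had 0 bp in both untreated and 2931 and 3206 bp in the treated libraries (adjusted p = 0.00327), and XAF1, a pro-apoptotic gene, 0 bp and then 2845 and 2648 bp (adjusted p = 3.29e-05). MX2, an antiviral GTPase that shares its window with FAM3B, had 0 bp and then 4548 and 2635 bp (adjusted p = 0.0403). FAM3B itself had 0 bp untreated and 3107 and 2574 bp treated (adjusted p = 0.00727). OAS2 rose by 2.66 ± 0.26 (adjusted p = 0.00217) and IFIH1, an RNA sensor that shares its window with GCA, by 2.51 ± 0.22 (adjusted p = 0.00157). MX1 rose by 1.98 ± 0.27 (adjusted p = 0.00861) and ISG15 by 1.11 ± 0.13 (adjusted p = 0.00341). IFIT1 (4345 and 4794 bp against 5564 and 6084 bp, adjusted p = 0.824) and IFIT3 (adjusted p = 0.976) were broadly covered before treatment and did not pass.

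Interferon signalling genes rose as a list in MiaPaCa2 (0.35 above other genes, 27 tested, camera adjusted p = 5.95e-07; adjusted p = 0.0696 with an estimated correlation), with 3 members higher over all genes and 9 adjusted over the list alone. Among them were USP18, which restrains receptor signalling (1.27 ± 0.18, adjusted p = 0.0109), and IRF1, from 6255 and 4803 bp to 9746 and 9781 bp (0.86 ± 0.14, adjusted p = 0.0214). IRF9 (1.5 ± 0.32, adjusted p = 0.097), SOCS1 (0.98 ± 0.30, adjusted p = 0.349), STAT2 (0.59 ± 0.17, adjusted p = 0.261) and IRF7 (-0.62 ± 0.41, adjusted p = 0.965) did not pass. The antigen presentation list rose by 0.32 above other genes (30 tested, camera adjusted p = 3.23e-09; adjusted p = 0.183 with an estimated correlation), with 5 members higher over all genes and 6 adjusted over the list alone. Among them TAP2 rose by 1.26 ± 0.13 (adjusted p = 0.00217), NLRC5 by 1.24 ± 0.18 (adjusted p = 0.0133), PSMB8 by 1.08 ± 0.10 (adjusted p = 0.00187) and PSMB9, which shares its window with TAP1, by 0.84 ± 0.12 (adjusted p = 0.00923). TAP2 and PSMB8 share a window too, so the members called over all genes, other than NLRC5, come in pairs with a shared window. The median change of the list was 0.115, with 27 members positive, against 0.03 over all genes. HLA-C (1.07 ± 0.22, adjusted p = 0.0716) and HLA-E (0.47 ± 0.19, adjusted p = 0.571) did not pass.

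In MiaPaCa2 87 genes gained and 14 lost covered length. Single members of lists that did not pass as a whole also rose. GATA6, an endodermal transcription factor, had 242 and 0 bp untreated and 831 and 955 bp treated (1.27 ± 0.16, adjusted p = 0.00627). CEACAM1, an adhesion gene, rose by 1.76 (adjusted p = 0.00245), and CDH3, which encodes P-cadherin, by 1.61 (adjusted p = 0.0183). ACSL5, a fatty acyl-CoA synthetase, had 0 bp untreated and 1058 and 924 bp treated (adjusted p = 6.57e-04). Coverage fell at LOC107984142 (-1.76 ± 0.31, adjusted p = 0.0391), C17orf99 (-1.71 ± 0.24, adjusted p = 0.0109), HOXA6, which shares its window with HOXA5 (-1.62 ± 0.28, adjusted p = 0.0348), SIGIRR, sharing with ANO9 (-1.5 ± 0.23, adjusted p = 0.0192), and GALNT15 (-1.5 ± 0.20, adjusted p = 0.008). With a -log10 q of at least 5 the fitted change at SIGIRR was 0.05 (adjusted p = 0.996). CACNA1G, a calcium channel gene, had 1240 and 795 bp untreated and 0 bp treated (adjusted p = 0.00627). CXCL10, KLF5, CDH1 and CDKN2A had 0 bp in all 4 libraries, and ELF3, VIM, ZEB1 and SMAD4 did not pass (adjusted p = 0.287 to 0.985). The other 18 lists did not pass; the nearest was sterol and fatty acid synthesis (-0.09, camera adjusted p = 0.0559), and the highest adjusted p was 0.912. Quantile normalization gave 107 gains and 49 losses. The count of 101 genes became 250 without untreated replicate 2, where losses outnumbered gains (121 gains and 129 losses). It was 33 without IFN-β replicate 1 (31 and 2), 142 without IFN-β replicate 2 (99 and 43), and 31 with only the libraries of this comparison, each a gain (limma, 845 genes at an unadjusted p under 0.05).

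Of 101815 loci in MiaPaCa2, 2342 were gained and 3351 lost, 5693 in all, a total close to the 4976 and 4919 of the other 2 divisions. Gained loci nevertheless lay near 33 of 70 interferon-stimulated genes (47.1%, against 9.4% of other genes; odds ratio 8.61, adjusted p = 1.04e-14; 5.38 times the matched number, adjusted p = 0.0042) and near 10 of 23 interferon signalling genes (odds ratio 7.31, adjusted p = 2.35e-04; matched adjusted p = 0.0063). The strongest gained loci were near NUP205 (chromosome 7, 135573440 to 135576740), SLC38A6, XAF1 (chromosome 17, 6754736 to 6757580), FAM133B, CUL5, MX2 (chromosome 21, 41360012 to 41362788), CAPZA1 and PLSCR1, an interferon-induced scramblase (chromosome 3, 146541749 to 146543921). The strongest lost loci, near TEF, OSCP1, CDA, PC, P2RX6, QSOX2, YJU2B and NRROS, had widths of 351 to 1066 bp. With the same number of peaks in each library 1762 loci were lost and 2930 gained. The odds ratio at interferon-stimulated genes was 5.43 without IFN-β replicate 1, 5.66 without untreated replicate 2 and 13.4 without IFN-β replicate 2. Gained and lost loci numbered 4676 and 13588 without untreated replicate 1, 4173 and 25541 without untreated replicate 2, 11348 and 4264 without IFN-β replicate 1, and 7036 and 8405 without IFN-β replicate 2.

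Whether the lines respond differently was tested as the difference between their changes in covered length. It passed at 9 genes, with 5 changes more positive in CFPAC1 and 4 more positive in MiaPaCa2. CXCL11 (difference 3.02 ± 0.35, adjusted p = 0.0158), MORC1 (adjusted p = 0.012), LINGO1, PNOC and APOBEC3A, a DNA deaminase gene (adjusted p = 0.0143 each) gained coverage in CFPAC1 and had 0 bp in all 4 MiaPaCa2 libraries. MORC1, LINGO1, PNOC and APOBEC3A also had 0 bp in untreated CFPAC1 and in the clones. They were tested only because both treated CFPAC1 libraries were covered. Groups at 0 bp add almost no spread to the shared estimate. These p-values therefore do not measure the spread between the treated libraries alone. XAF1 (-2.41 ± 0.19, adjusted p = 0.00322) and ACSL5 (-1.59 ± 0.18, adjusted p = 0.0143) were covered in untreated CFPAC1 and gained coverage from 0 bp in MiaPaCa2. CCDC33 (-1.88 ± 0.22, adjusted p = 0.0178) and TSPAN2 (-1.67 ± 0.23, adjusted p = 0.0487) lost coverage in CFPAC1. TSPAN2 had 0 bp in all 4 MiaPaCa2 libraries, where a loss could not be seen. Its difference therefore does not show that the lines respond differently. In the fit used throughout no list passed. Interferon-stimulated genes had a difference of -0.11 (camera adjusted p = 0.0734), with 1 member on each side over all genes and 7 more positive in CFPAC1 and 11 more positive in MiaPaCa2 adjusted over the list alone. The other 20 lists had adjusted p = 0.26 to 0.817. The difference was 2.79 ± 0.46 at CXCL10 (adjusted p = 0.0832), 1.28 ± 0.30 at IFIT1 (adjusted p = 0.247), -2.21 ± 0.46 at OAS1 (adjusted p = 0.154) and -0.45 ± 0.19 at IRF1 (adjusted p = 0.641). Quantile normalization gave 23 and 12 genes. With replicate number as a block 0 genes passed (limma, 1173 at an unadjusted p under 0.05). The 9 genes became 2, both more positive in MiaPaCa2, without either untreated CFPAC1 library or without CFPAC1 IFN-β replicate 1, and 0 without CFPAC1 IFN-β replicate 2 (limma, 1013 genes at an unadjusted p under 0.05). They became 21 and 24 without untreated MiaPaCa2 replicates 1 and 2, and 3 and 16 without treated MiaPaCa2 replicates 1 and 2. The list difference passed without CFPAC1 IFN-β replicate 1 (adjusted p = 6.68e-04), without untreated MiaPaCa2 replicate 1 (adjusted p = 0.00288) and without treated MiaPaCa2 replicate 2 (adjusted p = 7.76e-05), and was 0.05 without treated MiaPaCa2 replicate 1 (adjusted p = 0.854). It also passed with a -log10 q of at least 5 (adjusted p = 0.0287), the same number of peaks (adjusted p = 0.0157), a 2 kb window (adjusted p = 0.00633), no filter (adjusted p = 0.00202) and a pseudocount of 100 bp (-0.34, adjusted p = 1.78e-04). With a pseudocount of 2000 bp it was 0.00 (adjusted p = 0.557), and with an estimated correlation the adjusted p was 0.854.

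Gained loci were shared between the lines. Of 44918 loci present in both comparisons, 796 were gained in CFPAC1 and 1299 in MiaPaCa2, and 223 in both, where 23 were expected (odds ratio 15.6, adjusted p = 2.79e-154). Lost loci overlapped less, with 62 shared and 42.7 expected (odds ratio 1.5, adjusted p = 0.00519). Both expected numbers count loci held by every library of a comparison, which cannot be called. They may therefore be too low, and the odds ratios too high. Of the interferon-stimulated genes, 18 had a gained locus in both lines, among them MX1, OAS1, IRF7, GBP1 and RIGI. A further 17 had one in CFPAC1 alone, among them CXCL9, CXCL10, CXCL11 and CCL5, and 15 in MiaPaCa2 alone, among them MX2, XAF1, USP18, IFIH1 and STAT2 (exact sign test p = 0.86). The odds ratio for shared gained loci was 10.1 and 9.19 without untreated CFPAC1 replicates 1 and 2, 7.9 and 9.34 without treated CFPAC1 replicates 1 and 2, and 10.3 and 9.19 without untreated MiaPaCa2 replicates 1 and 2.

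**Figure D2:**
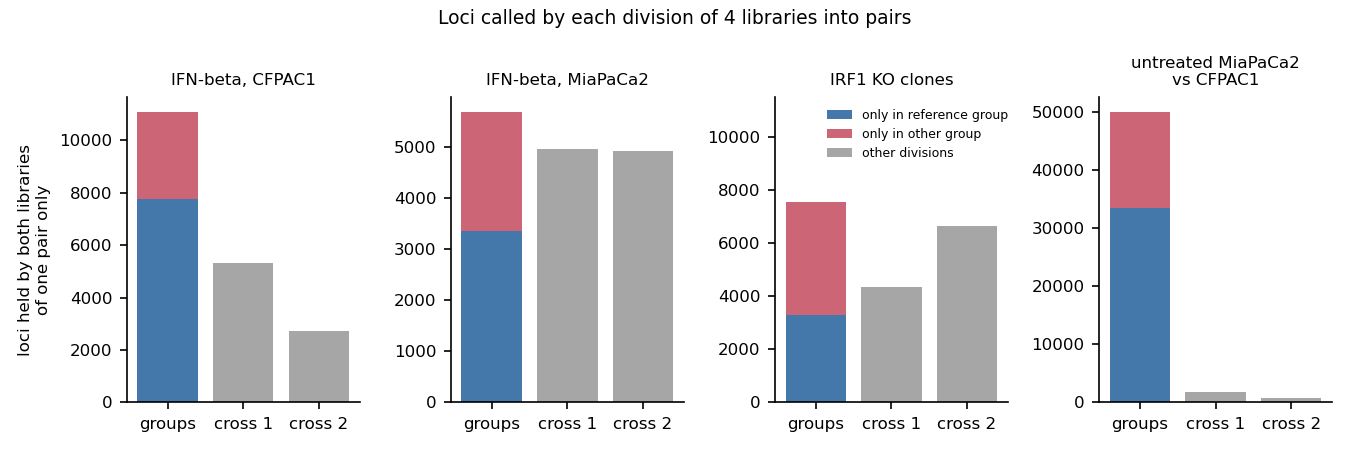
Number of loci (y axis, own scale in each panel) held by both libraries of one pair and neither of the other, for the division into groups and the other 2 divisions (cross 1 pairs libraries of the same replicate number, cross 2 of different numbers). The division into groups gave 11083, 5693, 7546 and 49935 loci, the highest of the other divisions 5328, 4976, 6634 and 1764.

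The comparison of IRF1 knockout with WT clones asked what the unstimulated landscape of CFPAC1 owes to IRF1. The 2 knockout clones had a Jaccard index of 0.576, below the median of 0.607 between groups of the same line, and knockout clone 2 had 0.496 to 0.576 with each other CFPAC1 library. The targeted gene itself had 5485 and 5611 bp covered in WT clones and 7533 and 8924 bp in knockout clones (0.41 ± 0.14, adjusted p = 0.208). Acetylation at the gene does not test the knockout, since CRISPR edits a few bases. Genes of classical pancreatic tumours, which mark the differentiated subtype, lost coverage as a list (-0.40 relative to other genes, 36 tested, camera adjusted p = 5.14e-05; adjusted p = 0.115 with an estimated correlation). Over all genes 4 members were lower, and 13 were lower and 1 higher adjusted over the list alone. CEACAM5, which encodes carcinoembryonic antigen, had 1106 and 1162 bp in WT clones and 0 bp in both knockout clones (adjusted p = 0.0105), and REG4, a secreted lectin, 886 and 1270 bp against 0 bp (adjusted p = 0.0171). LYZ, which encodes lysozyme, fell by 1.3 ± 0.26 on the log2 scale (adjusted p = 0.0468), LGALS4, a galectin, fell by 0.97 (adjusted p = 0.0274), and CTSE had 2953 and 2698 bp against 2313 and 593 bp (adjusted p = 0.242).

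Epithelial genes also lost coverage as a list in the knockout clones (-0.47 relative to other genes, 35 tested, camera adjusted p = 3.87e-05; adjusted p = 0.357 with an estimated correlation), although 0 members passed over all genes or over the list alone. Their members with the largest change were low in clone 2. GRHL2, a regulator of epithelial genes, had 7374 and 6433 bp in WT clones and 4830 and 299 bp in the knockout clones (adjusted p = 0.197), and ESRP1, a splicing factor, 4833 and 4278 bp against 4356 and 500 bp (adjusted p = 0.301). RAB25 had 2150 and 2147 bp against 1779 and 0 bp (adjusted p = 0.351), and OVOL1 2670 and 1983 bp against 1932 and 0 bp (adjusted p = 0.39). GRHL2 and ESRP1 lie on chromosome 8, where knockout clone 2 had 3% of its peaks against 4.01 to 4.62% in the other CFPAC1 libraries. Without knockout clone 1 the list difference was -0.69, without knockout clone 2 it was -0.23 (adjusted p = 0.00398). CDH1 was covered alike, 5177 and 5179 bp in WT and 4819 and 4582 bp in knockout clones (adjusted p = 0.38), and KLF5, ELF3, ZEB1, VIM and GATA6 did not pass (adjusted p = 0.134 to 0.855).

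Of the metabolic lists, 1 passed: sterol and fatty acid synthesis genes had less coverage in knockout clones (-0.24 relative to other genes, 38 tested, camera adjusted p = 8.25e-04; adjusted p = 0.357 with an estimated correlation). SCD, the desaturase of fatty acid synthesis, was its only member that passed, both over all genes and over the list alone (-0.37, adjusted p = 0.0453). HMGCS1, an enzyme of cholesterol synthesis (-0.76 ± 0.26, adjusted p = 0.224), FDFT1 (222 and 237 bp against 0 bp, adjusted p = 0.323) and SREBF2, the regulator of the pathway (-0.59 ± 0.20, adjusted p = 0.228), did not pass. The list difference was -0.14 without knockout clone 2 (adjusted p = 0.0444). Fatty acid oxidation (-0.03, camera adjusted p = 0.898), glycolysis and pentose phosphate (0.01, 0.831), TCA cycle and respiration (-0.07, 0.527), hexosamine and glycosylation (-0.16, 0.0999), amino acid metabolism (-0.04, 0.674) and glutathione and redox genes (0.08, 0.674) did not pass. Within the last list GPX3, a secreted glutathione peroxidase, rose by 1.28 (adjusted p = 0.0361), and GCLM also passed adjusted over the list alone (1.63, adjusted p = 0.0338).

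Interferon-stimulated genes did not pass in the knockout clones (-0.11 relative to other genes, 75 tested, camera adjusted p = 0.157), and 1 member, NMI, an interferon-induced adaptor, fell (-0.56, adjusted p = 0.0239). MX1 had 2038 and 1502 bp in WT and 1180 and 2892 bp in knockout clones, and OAS1 5508 and 2868 bp against 2113 and 4893 bp (adjusted p = 0.969 and 0.645). The list difference was -0.28 without knockout clone 2 (adjusted p = 1.92e-07), -0.15 without WT clone 2 (adjusted p = 0.0224) and 0.08 without knockout clone 1 (adjusted p = 0.2). Interferon signalling (0.04, camera adjusted p = 0.766), antigen presentation (-0.13, 0.119), NF-κB and inflammatory genes (0.03, 0.674), cell cycle (-0.11, 0.171), ribosomal proteins (-0.09, 0.157), endodermal factors (0.00, 0.766), mesenchymal genes (0.21, 0.119), the 3 lists of other cell types (0.20 to 0.28, 0.171 to 0.581) and the deletion genes (-0.04, 0.895) did not pass. Single members did: PROX1, an endodermal factor, rose by 1.57 (adjusted p = 0.0278), and PDGFRA, a growth factor receptor of mesenchymal cells, by 1.72 (adjusted p = 0.0275). PDGFRA lies on chromosome 4, which held 3.91% of the peaks of WT clone 1 against 4.91 to 5.65% in the other CFPAC1 libraries. ZEB2, SNAI1 and PRRX1 of the mesenchymal list passed adjusted over the list alone (0.75, 1.16 and 1.07; adjusted p = 0.0309, 0.0309 and 0.0364). SNAI1 lies on chromosome 20.

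In all, 110 genes gained and 84 lost coverage in the knockout clones. The largest gains were at BMP2, a growth factor of the TGF-β family (0 bp in WT, 2383 and 2319 bp in knockout clones, adjusted p = 0.00515), PDE3A, a phosphodiesterase (0 bp against 2031 and 2495 bp, adjusted p = 0.00558), and INSYN2B (0 bp against 938 and 3886 bp, adjusted p = 0.0367). They were followed by C10orf90 (2.14 ± 0.34, adjusted p = 0.0239), HEG1 (0 bp against 1691 and 1528 bp, adjusted p = 0.032) and PLPP4, a lipid phosphatase (0 bp against 1432 and 1768 bp, adjusted p = 0.00515). The largest losses were at TMPRSS4, a membrane protease (-2.81 ± 0.35, adjusted p = 0.0115), RBBP8, a DNA repair gene (2801 and 1594 bp against 0 bp, adjusted p = 0.00515), and CEACAM3 (-2.33 ± 0.42, adjusted p = 0.0343). LOC105373071 (-2.27 ± 0.21, adjusted p = 0.00515), UNC13C (-2.22 ± 0.36, adjusted p = 0.024) and GJB1, a gap junction gene (-2.14 ± 0.35, adjusted p = 0.0246), fell too. BMP2 lies on chromosome 20, whose share of peaks was 2.05% in WT clone 2 and 2.62 to 3.48% in the other CFPAC1 libraries. Without centring 150 genes gained and 46 lost coverage, with the median shifted by 0.111, and quantile normalization gave 75 gains and 87 losses. The count of 194 was 151 without WT clone 1 (109 gains and 42 losses) and 32 without WT clone 2 (19 and 13). Losses outnumbered gains without knockout clone 1, the library whose background level could not be solved (733 genes, 304 and 429), and without knockout clone 2 (48 genes, 16 and 32). The count was 114 without the 5 chromosomes of unusual peak share, an alternative chosen after seeing the data, and 0 with only the 4 clone libraries (limma, 1319 genes at an unadjusted p under 0.05). With only the clone libraries the spread comes from the clones alone, while the main fit shares it with the bulk groups.

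**Figure D3:**
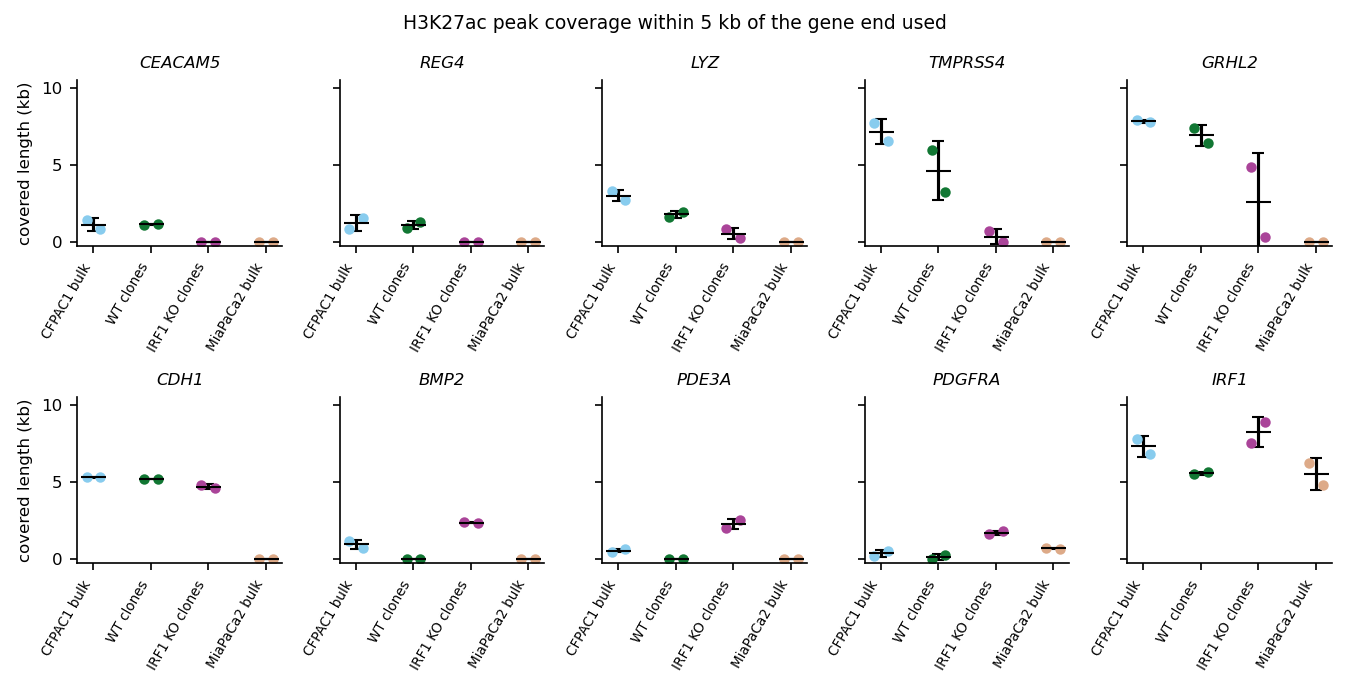
Covered length (kb, y axis) around 10 genes in bulk untreated CFPAC1, WT clones, IRF1 knockout clones and bulk untreated MiaPaCa2; points are the 2 libraries of a group, bars the mean and SD. CEACAM5 and REG4 had 0 bp in both knockout clones, while GRHL2 had 4830 bp in knockout clone 1 and 299 bp in knockout clone 2.

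Between the clones 4240 loci were gained and 3306 lost in the knockout, of 126348 in all. Their total of 7546 compares with 4344 and 6634 in the other 2 divisions. With the same number of peaks in each library it was 6978 against 4117 and 4996, with 3333 gained and 3645 lost, so the balance turned. The strongest gained loci were near RAB40B, PPARGC1A, a coactivator of mitochondrial metabolism (chromosome 4, 24472596 to 24473695), SPATA18, SPTBN1, RHOJ, PDE3A (chromosome 12, 20367769 to 20370269), LRIG1 and BMP2 (chromosome 20, 6767919 to 6768360). The strongest lost loci were near TPRG1 (chromosome 3, 189333459 to 189336467), PHKA1, MAX, KLK10, ANXA8, CEACAM5 (chromosome 19, 41734674 to 41735728), ZNF487 and FBRSL1. Lost loci lay near 11 of 33 classical tumour genes (odds ratio 4.31, adjusted p = 0.00716; matched adjusted p = 0.176), and gained loci near 13 of 36 mesenchymal genes (odds ratio 3.5, adjusted p = 0.0156; matched adjusted p = 0.299). Lost loci near interferon-stimulated genes had an odds ratio of 0.909 (adjusted p = 1), and of 0.51 without WT clone 1. Over the alternatives other than leaving out a library the value ranged from 0.611 to 1.53 (lowest adjusted p = 0.72). On chromosome 20, 8.55% of loci were gained and 0.22% lost. Chromosomes 2, 4 and 5 also had more loci gained (2.64, 3.99 and 4.71%) than lost (1.67, 1.22 and 1.78%), and chromosome 8 fewer (2.57% against 4.88%). All of these are among the 5 chromosomes of unusual peak share. PPARGC1A and SPATA18 lie on chromosome 4 and SPTBN1 on chromosome 2. Gained and lost loci numbered 8894 and 10165 without WT clone 1, 6230 and 14951 without WT clone 2, 33212 and 6782 without knockout clone 1, and 10664 and 6766 without knockout clone 2.

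Loci that IFN-β gained in CFPAC1 were not among those lost with IRF1 more often than by chance: 25 of 871 were, where 29.2 were expected (odds ratio 0.851, p = 0.507 by Fisher's exact test). This overlap cannot test whether the gains depend on IRF1, since the calls work against each other. A gained locus has no peak in either untreated CFPAC1 library, while a lost locus has one in both WT clones, also unstimulated CFPAC1 cells. The knockout clones were not treated with IFN-β. The odds ratio rose above 1 without untreated CFPAC1 replicate 2 (1.53), WT clone 1 (2.39) or WT clone 2 (1.74). It was 0.642 without knockout clone 1 and 0.801 without IFN-β replicate 2. Over the alternatives other than leaving out a library it ranged from 0 to 1.21 (lowest Fisher's exact p = 0.0836). Other pairs shared more loci than the test expects, but their calls lean the same way by construction. Lost loci of both comparisons need peaks in unstimulated CFPAC1 cells with IRF1 intact, and gained loci of both need none there. These overlaps therefore do not show a shared effect. In all, 267 loci were lost both after IFN-β and in knockout clones, where 212 were expected (odds ratio 1.29, adjusted p = 2.04e-04), and 52 were gained in both, where 25.1 were expected (odds ratio 2.16, adjusted p = 2.9e-06).

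Untreated MiaPaCa2 differed from untreated CFPAC1 across the genome, a comparison of lines that were also grown in different media. Several epithelial and endodermal genes were covered in CFPAC1 and had little or no coverage in MiaPaCa2. CDH1, which encodes E-cadherin, had 5312 and 5287 bp in CFPAC1 and 0 bp in MiaPaCa2 (adjusted p = 2.03e-08), KLF5 8379 and 8112 bp against 0 bp (adjusted p = 2.03e-06), and GRHL2 7889 and 7761 bp against 0 bp (adjusted p = 6.18e-04). The endodermal transcription factor FOXA1 likewise had 5487 and 4404 bp against 0 bp (adjusted p = 1.06e-05), and GATA6 had 4568 and 4674 bp against 242 and 0 bp (-3.01 ± 0.16, adjusted p = 4.62e-07). VIM, the mesenchymal filament gene, was broader in MiaPaCa2, with 3953 and 3729 bp in CFPAC1 and 8667 and 9407 bp in MiaPaCa2 (1.19 ± 0.09, adjusted p = 3.51e-06).

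Classical tumour genes were lower in MiaPaCa2 as a list (-1.87 relative to other genes, 36 tested, camera adjusted p = 1.51e-11; adjusted p = 0.0117 with an estimated correlation), with 3 members higher and 26 lower over all genes, and 4 and 27 adjusted over the list alone. TSPAN8, ANXA10, GALNT5 and MUC4 had 4842 to 7800 bp in CFPAC1 and 0 bp in MiaPaCa2. Endodermal factors had a difference of -1.45 (24 tested, camera adjusted p = 7.37e-07; adjusted p = 0.0163 with an estimated correlation), with 1 member higher and 13 lower, as adjusted over the list alone. Epithelial genes had -1.48 (35 tested, camera adjusted p = 2.3e-06; adjusted p = 0.19 with an estimated correlation), with 2 higher and 19 lower, the same numbers adjusted over the list alone. MAL2 went from 9023 and 9428 bp to 0 bp and LAMB3, a laminin chain, from 9924 and 10001 bp to 0 and 693 bp. Hexosamine and glycosylation genes had -1.01 (33 tested, camera adjusted p = 9.67e-05; adjusted p = 0.19 with an estimated correlation), with 4 higher and 17 lower on both adjustments. FUT8, ST6GALNAC1 and GCNT3 had 4869 to 9012 bp in CFPAC1 and 0 bp in MiaPaCa2. Mesenchymal genes did not rise as a list (-0.38, 32 tested, camera adjusted p = 0.0882), with 8 members higher and 14 lower over all genes and 9 and 15 adjusted over the list alone. ZEB1 had 4434 and 5683 bp in CFPAC1 against 3231 and 3850 bp (adjusted p = 0.0524).

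Interferon-stimulated genes were also less covered in untreated MiaPaCa2 (-0.77, 75 tested, camera adjusted p = 4.98e-07; adjusted p = 0.438 with an estimated correlation), with 4 higher and 39 lower on both adjustments. SAMD9, an antiviral factor (4905 and 5347 bp), OAS1 (5251 and 3656 bp) and XAF1 (3759 and 4074 bp) had 0 bp in MiaPaCa2 (adjusted p = 9.88e-08 to 3.19e-05), and APOL1 fell by 3.32 ± 0.32 on the log2 scale (adjusted p = 2.32e-05). IFIT1 went the other way (1.12 ± 0.21, adjusted p = 0.00184), and ISG15 was lower (-0.43 ± 0.13, adjusted p = 0.0171). IRF1, STAT2, IRF7, IRF9, IFIT3, MX1 and CXCL10 did not pass (adjusted p = 0.0781 to 0.911). Antigen presentation genes had -0.50 (30 tested, camera adjusted p = 0.00751; adjusted p = 0.438 with an estimated correlation), with 6 higher and 14 lower over all genes and 6 and 17 adjusted over the list alone. CD74, the class II invariant chain (4598 and 4024 bp), HLA-DPB1 and HLA-DPA1, which share a window (962 to 1633 bp), and HLA-F (1205 and 1135 bp) had 0 bp in MiaPaCa2 (adjusted p = 1.8e-07 to 0.00253). HLA-E fell by 0.66 ± 0.19 on the log2 scale (adjusted p = 0.0157) and PSMB9 by 0.57 ± 0.12 (adjusted p = 0.00279). This call was lost over the whole gene with 5 kb flanks, a window chosen after seeing the data (adjusted p = 0.0534). Ribosomal protein genes, written down as a control list, were broader in MiaPaCa2 (0.53, 35 tested, camera adjusted p = 9.67e-05, or 0.379 with an estimated correlation). Over all genes 23 were higher and 1 lower, and 24 and 1 adjusted over the list alone, among them RPL38, sharing a window with TTYH2 (2.34 ± 0.27), RPS15 (1.56 ± 0.13) and RPS7 (1.14 ± 0.13). Since a control list moved, list differences between the lines may hold a general difference in peak breadth at gene ends, which was not tested. The other 13 lists did not pass (camera adjusted p = 0.0939 to 0.945).

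Across all genes 4500 were more and 3080 less covered in MiaPaCa2. Genes with 0 bp in CFPAC1 and 8556 to 10001 bp in MiaPaCa2 were CAVIN2, ALDH8A1, FEZ2, BEGAIN, ADTRP and KANK4 (adjusted p = 2.75e-08 to 0.00202). Genes with 9299 to 10001 bp in CFPAC1 and 0 bp in MiaPaCa2 were ADGRF1, PADI1, B4GALT4, LIPH, SOX2 and TMEM156 (adjusted p = 8.23e-09 to 1.22e-08). CDKN2A, the cell cycle inhibitor often deleted in pancreatic cancer, had 6138 and 6461 bp in CFPAC1 and 0 bp in MiaPaCa2 (adjusted p = 8.65e-09), while SMAD4, the TGF-β effector, had 0 bp in CFPAC1 and 2241 and 2095 bp in MiaPaCa2 (adjusted p = 2.47e-06). Loci present in CFPAC1 alone numbered 33493 and in MiaPaCa2 alone 16442, of 159828, a total of 49935 against 1764 and 791 in the other divisions. The strongest MiaPaCa2 loci were near WDR25, METTL4, POU5F1B (chromosome 8, 127387056 to 127405829), DOCK11, PDGFC, BEGAIN, PIP5K1C and FBXO17. The strongest CFPAC1 loci were near ACSL5 (chromosome 10, 112373499 to 112380212), PLAAT4, HSPA1B, PCED1B, APOL1, PADI1, ANKRD1 and AADACL2. CFPAC1 loci lay near 45 of 71 interferon-stimulated genes (odds ratio 2.36, matched adjusted p = 0.0042) and 25 of 33 classical tumour genes (odds ratio 4.26, matched adjusted p = 0.049), and near 5 of 34 ribosomal protein genes (odds ratio 0.234, matched adjusted p = 0.0252). MiaPaCa2 loci lay near 2 of 33 classical tumour genes (odds ratio 0.168, matched adjusted p = 0.0084). Without untreated CFPAC1 replicate 1 the CFPAC1 loci numbered 57526, and without untreated MiaPaCa2 replicates 1 and 2 the MiaPaCa2 loci numbered 30492 and 43608.

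**Figure D4:**
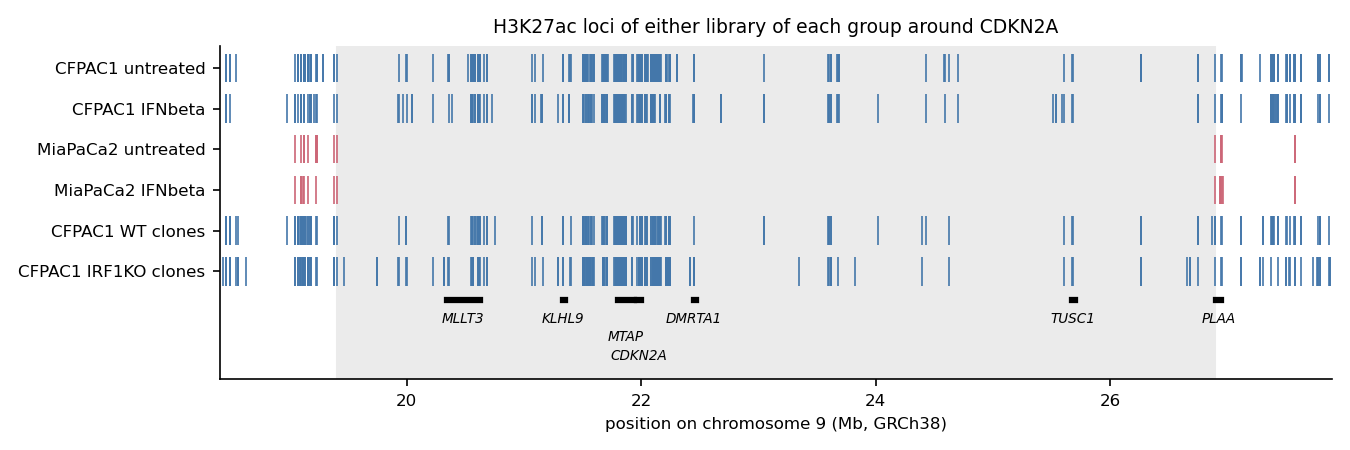
Positions of H3K27ac loci (vertical marks, x axis in Mb of chromosome 9) held by either library of each of the 6 groups (y axis), with genes as bars and the stretch without any MiaPaCa2 peak in grey. The grey stretch runs from 19409826 to 26890883 and holds 45 loci of CFPAC1, CDKN2A and MTAP among the genes.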

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

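The genes below came from a test planned before the data were examined; the weighing of 3 patterns uses tests chosen after the patterns were seen, of which only the tests of copy number had their predictions written before the values were computed. A limma test of the difference between CFPAC1 and MiaPaCa2 in the change after IFN-β picked out 9 genes. With replicate number as a block it picked out 0 genes. At CXCL11, CFPAC1 coverage went from 56 and 296 bp to 5785 and 3729 bp and MiaPaCa2 stayed at 0 bp (adjusted p = 0.0158). MORC1 had 3432 and 2574 bp in treated CFPAC1 and 0 bp elsewhere in this comparison (adjusted p = 0.012). LINGO1 had 5982 and 3300 bp in treated CFPAC1 and 0 bp elsewhere (adjusted p = 0.0143). APOBEC3A had 2040 and 1738 bp in treated CFPAC1 and 0 bp elsewhere (adjusted p = 0.0143). PNOC had 1706 and 2090 bp in treated CFPAC1 and 0 bp elsewhere (adjusted p = 0.0143). MORC1, LINGO1, APOBEC3A and PNOC had 0 bp in the clones too, and met the filter only through the treated CFPAC1 libraries. XAF1 had 3759 and 4074 bp in untreated and 4755 and 4588 bp in treated CFPAC1, against 0 bp and then 2845 and 2648 bp in MiaPaCa2 (adjusted p = 0.00322). ACSL5 had 6293 and 5590 bp and then 5539 and 5661 bp in CFPAC1, against 0 bp and then 1058 and 924 bp in MiaPaCa2 (adjusted p = 0.0143). CCDC33 went from 7451 and 4984 bp to 1172 and 1054 bp in CFPAC1 and from 9911 and 9443 bp to 8728 and 9432 bp in MiaPaCa2 (adjusted p = 0.0178). TSPAN2 went from 1865 and 1953 bp to 229 and 223 bp in CFPAC1 and had 0 bp in MiaPaCa2, where a loss could not be seen (adjusted p = 0.0487).

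After IFN-β, CFPAC1 lost 2.32 loci for each locus gained. With the same number of peaks in each library this ratio was 1.12, but that step itself moves the ratio towards 1, so shorter peak lists in the treated libraries are left open. Lower depth of the treated libraries is left open: their background level, a stand-in for depth, was 0.912 of the untreated level, but the depth itself is unknown. A loss of acetylation by the treatment is also left open, since 8802 loci were called with equal peak numbers, above the 5257 of the highest other division, while 2 libraries against 2 cannot give a small permutation p.

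Classical tumour and epithelial genes had less coverage in IRF1 knockout clones as lists, but neither list passed with an estimated correlation (camera adjusted p = 0.115 and 0.357). With the preset correlation, the 5 chromosomes of unusual peak share do not account for all of it. Without them the classical list differed by -0.39 and the epithelial list by -0.37 (camera adjusted p = 0.00102 for each). Copy number itself was not measured. Changes in part of a chromosome, or on the chromosomes kept, would not be seen in this way and are left open. Knockout clone 2 is not the whole cause, since without it the classical list differed by -0.34 (adjusted p = 5.92e-05) and the epithelial list by -0.23 (adjusted p = 0.00398). Loss of IRF1 itself is left open, since the smallest permutation share of 2 clones against 2 is 0.333 and clones differ for many reasons.

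On chromosome 20, 8.55% of loci were gained and 0.22% lost in the IRF1 knockout clones. A difference in copy number predicts a shift along the whole chromosome, and 7 of its 7 segments of 10 Mb had a median change above that of all genes. The median over its genes was 0.25, against -0.05 for all genes and 0.035 for the chromosome next in order. Loss of IRF1 was not tested for this pattern and is left open, since clones differ for many reasons.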

How the results depend on the processing

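Of 226 combinations of a main result and an alternative other than leaving out a library, 184 stayed on the same side of the threshold or within 1.5 times the main count. In the others 29 moved, 10 became stronger, 3 weaker and 0 reversed. A turned direction counts as reversed only where the main result or the alternative passed. Among those counted as kept, the odds ratio of loci gained with IFN-β and lost with IRF1 ranged from 0 to 1.21 (main 0.851). That of lost loci near interferon-stimulated genes in knockout clones ranged from 0.611 to 1.53 (main 0.909). The list of interferon-stimulated genes passed after IFN-β in both lines, in covered length and in gained loci, under every alternative but the estimated correlation. Calls of single genes held less well. Over all alternatives, leaving out a library included, called genes picked for naming kept their call in 226 of 330 combinations of gene and setting in CFPAC1, 261 of 352 in MiaPaCa2, 106 of 170 in the difference, 187 of 261 in knockout clones and 692 of 705 between lines. Unless a reason is given, the cause of a change was not tested. Depth is unknown, so what it limits could not be measured. Motif searches and their alternatives were not run.

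With a -log10 q of at least 5, which leaves fewer peaks, gained loci in CFPAC1 numbered 2209 and lost loci in MiaPaCa2 1397, knockout clones lost 2111, MiaPaCa2 alone held 8907, and the response differed at 17 genes. With the same number of peaks, 4641 loci were lost in CFPAC1 and 1762 in MiaPaCa2. With a strict presence against no deposited peak, which asks more of a locus, gained and lost loci numbered 1388 and 2091 in CFPAC1, 785 and 428 in MiaPaCa2 and 1376 and 951 in knockout clones, and 21793 and 7461 were in CFPAC1 or MiaPaCa2 alone. The response differed at 27 genes with a pseudocount of 100 bp, 21 with 2000 bp, 57 without the filter, 17 without centring, 35 with quantile normalization (156 genes changed in MiaPaCa2) and 19 with only the libraries of the comparison. These last gave 46 genes in CFPAC1, 31 in MiaPaCa2 and 0 in knockout clones (limma, 1319 at an unadjusted p under 0.05). Such fits have fewer residual degrees of freedom and take their spread from their own libraries alone. Which of these lowered the counts was not tested. Without the 5 chromosomes of unusual peak share, chosen after seeing the data and leaving fewer genes, 114 genes changed in knockout clones.

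The difference between lines at interferon-stimulated genes, -0.11, passed with a -log10 q of at least 5 (-0.107), the same number of peaks (-0.133), a 2 kb window (-0.161), a pseudocount of 100 bp (-0.335), no filter (-0.125) and, chosen after seeing the data, the whole gene with flanks (-0.217). In knockout clones the list passed with quantile normalization (-0.138). Mesenchymal genes between lines passed with a pseudocount of 100 bp (-0.63) and over the whole gene (-0.477). An estimated correlation left interferon-stimulated genes at 0.961 in CFPAC1 (adjusted p = 0.224) and 1.07 in MiaPaCa2 (adjusted p = 0.0667), and epithelial genes between lines at -1.48 (adjusted p = 0.19). The sign turned for B3GNT6 in CFPAC1 with the same number of peaks (0.106, adjusted p = 0.964) and for SIGIRR in MiaPaCa2 with a -log10 q of at least 5 (0.053, adjusted p = 0.996).

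Same-numbered libraries share only a number; the correlations of their deviations were 0.205 in CFPAC1, -0.011 in MiaPaCa2 and -0.057 in the clones. With a replicate block, 65 genes changed in CFPAC1, 28 in knockout clones, and 0 differed in response (limma, 1173 at an unadjusted p under 0.05), while the list difference was -0.11 (adjusted p = 0.0457). No paired analysis was possible for the lines because nothing pairs them, nor for counts of loci because they come from no test.

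Leaving out 1 library loosens the definition of a locus, and in limma the lone library is assumed to vary like the other groups. Over these fits gained loci ranged from 4550 to 11160 and lost from 11721 to 26914 in CFPAC1, from 4173 to 11348 and 4264 to 25541 in MiaPaCa2, and from 6230 to 33212 and 6766 to 14951 in knockout clones; CFPAC1 alone held 35338 to 57526 and MiaPaCa2 alone 17939 to 43608. Odds ratios at interferon-stimulated genes ranged from 4.04 to 7.22 and from 5.43 to 13.4, and in lost loci of knockout clones from 0.51 to 1.27. Shared gained loci had odds ratios of 7.9 to 22.4, and loci gained with IFN-β and lost with IRF1 of 0.642 to 2.39, reversed at 1.53, 1.74 and the highest value (Fisher's exact p = 5.59e-06, 4.81e-08 and 1.99e-16). Changed genes numbered 3 to 70 in CFPAC1, 33 to 250 in MiaPaCa2, 0 to 24 in the difference (limma, 1013 unadjusted at 0), 32 to 733 in knockout clones and 5662 to 6334 between lines. List differences ranged from 0.86 to 1.049 and 0.908 to 1.234 for interferon-stimulated genes in CFPAC1 and MiaPaCa2, -0.272 to 0.053 for their difference, -0.284 to 0.079 in knockout clones, and between lines -1.526 to -1.432 for epithelial and -0.436 to -0.328 for mesenchymal genes. Of called genes picked for naming, those that kept their call without replicates 1 and 2 numbered as follows. The total is smaller where a gene covered in 2 libraries alone no longer met the filter. In CFPAC1 they were 8 and 9 of 21 (untreated) and 2 and 11 of 19 (treated), and in MiaPaCa2 14 and 18 (untreated) and 6 and 17 (treated) of 22. In the difference they were 2 and 2 of 9 (untreated CFPAC1), 1 and 0 of 5 (treated CFPAC1, limma, 1013 genes unadjusted at 0), 8 and 8 of 9 (untreated MiaPaCa2) and 2 and 6 of 9 (treated MiaPaCa2). Among the clones they were 10 and 6 of 15 (WT) and 13 and 6 of 13 (knockout), and between the lines 45 and 46 (CFPAC1) and 45 and 47 (MiaPaCa2) of 47.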

Other observations

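Between the untreated lines, single genes of lists that did not pass as a whole differed in both directions. The mesenchymal list was mixed: COL3A1, a fibrillar collagen, had 0 bp in CFPAC1 and 4183 and 5033 bp in MiaPaCa2 (limma adjusted p = 3.79e-07), and SNAI1, a repressor of CDH1, was higher in MiaPaCa2 by 2.03 (adjusted p = 1.38e-04). SNAI2, its relative, was lower (-2.25, adjusted p = 1.71e-06), and CDH2, which encodes N-cadherin, had 1526 and 4044 bp in CFPAC1 and 0 bp in MiaPaCa2 (adjusted p = 1.27e-04). The NF-κB and inflammatory list was mixed too, with 7 members higher and 12 lower in MiaPaCa2: ICAM1 was higher by 2 (adjusted p = 7.38e-04) and TNF by 1.52 (adjusted p = 0.00218), while genes covered in CFPAC1 and not in MiaPaCa2 included IL6 (3641 and 5879 bp, adjusted p = 8.36e-07) and PTGS2, which makes prostaglandins (2744 and 4141 bp, adjusted p = 4.02e-05). Among metabolic genes, KYNU of tryptophan breakdown (8225 and 8890 bp, adjusted p = 8.23e-09) and LDHB, a lactate dehydrogenase (2978 and 3170 bp, adjusted p = 3.79e-07), were covered in CFPAC1 and had 0 bp in MiaPaCa2. ACADVL, an enzyme of fatty acid oxidation, was higher in MiaPaCa2 by 1.585 (adjusted p = 1.46e-04). These genes were chosen after their values were seen.

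Genes around CDKN2A had no peak in any MiaPaCa2 library. The stretch without peaks is 7.48 Mb long (chromosome 9, 19409826 to 26890883) and spans 31 genes, among them MTAP, KLHL9, CDKN2B, DMRTA1 and the type I interferon genes, IFNB1 included. The hypothesis of a deletion in MiaPaCa2, made after the pattern was seen, predicts that few other stretches hold as many gene-end loci of CFPAC1. It ranked 1 of 4769 stretches, by gene-end loci and by all loci, with 9 gene-end loci among its 45 loci. For SMAD4 in CFPAC1 the stretch is 313.5 kb long (chromosome 18, 50880612 to 51194130), holds 3 loci of MiaPaCa2, each at a gene end, and ranked 9 of 2979 by gene-end loci but 474 by all loci. SMAD4 and its neighbour ELAC1 had 0 bp in all 8 CFPAC1 libraries, while ELAC1 had 1789 and 1936 bp in untreated MiaPaCa2. The rank for CDKN2A is in line with a deletion, while SMAD4 is left open, and peak lists cannot separate a deleted from a silent region.

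A hypothesis made after seeing the data was that the knockout clones, rather than the WT clones, departed from bulk CFPAC1. Of loci over 1 kb from any gene end that were lost in the knockout clones, 53.9% were held by both untreated bulk CFPAC1 libraries, against 20.6% of those gained and 28 to 38.4% of sets from the other divisions of the clones. Against the pooled sets (31.7%) the odds ratios were 2.52 for lost and 0.561 for gained loci (Fisher's exact test adjusted p = 8.54e-109 and 2.68e-37), with loci taken as independent. Sets with knockout clone 1 had 38.4 and 38.3%, and sets with knockout clone 2 had 29.8 and 28%, so the 2 knockout clones differed. WT clones also departed in shares of peaks. WT clone 2 had 0.7 times the mean share of the other CFPAC1 libraries on chromosome 20, and WT clone 1 had 0.75 times on chromosome 4. The shares of distal loci fit the hypothesis, though with 2 clones of each kind they do not tie the departure to IRF1. A move of the knockout clones towards MiaPaCa2 is left open. Both untreated MiaPaCa2 libraries held 15.4% of the gained loci, no more than of the pooled sets (15.5%, odds ratio 0.991, adjusted p = 0.872). They held fewer of the lost loci than of the pooled sets (11.6%, odds ratio 0.716, adjusted p = 5.58e-08). Both shares lie within the 11.3 to 17.2% of single sets from the other divisions.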
